A study of Mus musculus with 12 samples.

How the data were processed

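Poly(A) RNA was sequenced from 12 libraries of aggregates grown from the mouse embryonic stem cell line 129w2. Per the labels, they form 4 groups of 3 libraries: aggregates co-cultured with mSMGs, an abbreviation the labels do not spell out, from day 5 to day 7, with their own controls, and aggregates given a mixture of factors (the cocktail) with their own controls. The composition of the cocktail is not given in the sources used here. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

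The submitters' processing notes name HISAT2 and the genome build GRCm38, without a version. The quantifier, the annotation and the tool behind the authors' comparison are not given in the sources used here. For the co-culture experiment the authors deposited values per library for 546 genes, and a panel of 12 of them whose values were identical. The header of that table gives no unit. The values have decimals, do not share a total and lie near the FPKM of the other experiment for genes in both tables (Pearson r 0.86 between log2 means of the controls, across genes), so the unit FPKM (fragments per kilobase of transcript, scaled to library size) is inferred here for the deposited values. For the cocktail experiment the deposited table gives FPKM per the file headers, the authors' log2 fold change and the authors' adjusted p-value (FDR) for 633 genes. Every one of these genes has an FDR of at most 0.0099 and an absolute log2 fold change of at least 1.002. A smaller deposited sheet holds a panel of 15 genes, of which 8 are outside the list of changed genes. For 10 of its genes the values stand a column away from their header, and they were read from there after checking that all 10 equal the same genes' values given again at the foot of the sheet. The authors also deposited a pathway enrichment of genes named as up in co-culture, with p-values, q-values, a ratio (the enrichment factor) and numbers of genes.

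Both tables therefore hold genes chosen by the authors, and neither is a sample of all genes. In the cocktail table, the column names give the group but match no sample title, so its columns were used as 3 unnumbered replicates per group. The 6 count columns of that table were not used, and the fit ran on its FPKM columns. A further 6 columns named only by numbers were not used. The depth of the libraries was not analysed here, and the number of libraries limits the precision. Gene symbols were taken from GENCODE M21 (GRCm38) by gene identifier: 546 of 546 co-culture genes and 594 of 633 cocktail genes matched. The other 39 cocktail genes carry identifiers of new transcripts and no symbol. They were tested and counted but not named.

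Each experiment was fitted alone, since the tables were normalized separately. The test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(value + 1), over genes with a mean of at least 1 in either group. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The design written beforehand named this test for normalized values and for tables of selected genes. The test script was tested on simulated data with 200 changed genes per experiment. For 425 simulated co-culture genes it recovered 14.8% of changes of size 1 on the log2 scale and 76.8% of those of size 2, with false calls in 2.67% of unchanged genes. For 536 simulated cocktail genes it recovered 98.9% and 100%, with false calls in 2.08%. The simulation drew noise independently for each gene and did not select genes. In the deposited tables genes were selected and a library can differ across many genes together, so these rates may not carry over.

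The co-culture groups share the replicate numbers 1 to 3. Deviations from the group means correlated between same-numbered libraries at 0.606, 0.143 and 0.256 across genes, against at most 0.042 between libraries of different numbers. By the rule set for this check (every pair over 0.1), the numbers were treated as pairs. The check cannot establish pairing: deviations within a group sum to 0, so these correlations depend on each other. The genes also appear to have been chosen on pairs 1 and 2, which can raise those 2 correlations and, through the sum, that of pair 3. The blocked value is therefore given beside the main one.

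Before the data were examined, 33 gene lists with 428 genes were fixed, and their members past the threshold were counted over all genes tested and adjusted over the list alone. Within the cocktail list, the pathway annotation that the authors deposited was tested for an unequal split between higher and lower genes with Fisher's exact test (two-sided, scipy 1.17.1, 110 pathways with at least 5 annotated members, Benjamini-Hochberg adjusted). The background was the 327 annotated genes of the list. Agreement between experiments was measured by Spearman correlation of log2 fold changes across genes tested in both, which are not replicates. The controls of the 2 experiments are different libraries.

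The genes named are the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, without predicted genes. To these come up to 4 members, by smallest adjusted p, of each fixed list with 3 or more members past the threshold, 12 genes named in any case, and all genes of a table with under 40 genes. Of the 12, the co-culture table holds Sox10 and Fgf10 and that of the cocktail Fgf10. The others were not analysed here. No co-culture gene passed without the block, so the co-culture genes were named by the same rule from the blocked fit, a choice made after seeing the data. Other genes outside the rule, such as those of the deposited pathways, were chosen after their values were seen. Some genes that the rule names are not reported here.

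Alternatives left out each replicate, required an absolute log2 fold change of at least 1 or an adjusted p under 0.01, quantile-normalized the values, removed the filter or raised it to a mean of 5, lowered the pseudocount to 0.1, dropped the intensity trend, used the authors' own list, or added the replicate block. Their effect is given in the closing section.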

Results

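Aggregates of mouse embryonic stem cells were profiled by RNA-seq in 2 experiments with 3 libraries per group. The cells were from the line 129w2, and 3000 cells per well were aggregated on day 0. All aggregates received BMP4 (2 ng/ml) on day 3, basic FGF (25 ng/ml) and retinoic acid (1 µM) on day 4, and a new plate on day 5. In the first experiment, aggregates were co-cultured with mSMGs from day 5 to day 7 and compared with aggregates at day 7. The second experiment compared aggregates given a cocktail of factors with aggregates at day 7. For the cocktail libraries the labels give no day of collection and no start or end of exposure. A difference in stage from their controls therefore cannot be told apart from an effect of the cocktail. Per the series design, the cocktail was meant to take the place of co-culture. The values are FPKM (inferred for the co-culture table, whose header gives no unit) for genes that the authors selected, 546 in the co-culture table and 633 in the cocktail list. Counts of changed genes below describe these selected sets and not the transcriptome. The depth of each library was not analysed here.

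Over the selected genes, libraries of the same group were closer to each other in the cocktail experiment than in the co-culture experiment. The cocktail genes were listed for a low FDR and a large fold change, which favours close replicates and distant groups. The correlations therefore do not compare the quality of the 2 experiments. Across the genes of the cocktail table, log2(FPKM + 1) correlated at 0.988 to 0.991 within groups and at 0.454 to 0.477 between groups. In the co-culture table the controls correlated at 0.923 to 0.954. Co-culture replicates 1 and 2 correlated at 0.911. Co-culture replicate 3 correlated at 0.867 and 0.748 with the other co-culture libraries and at 0.965 with control replicate 3. No 2 libraries held identical values.

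The first comparison asked how the co-culture libraries differed from their controls. Whether RNA of the mSMGs themselves entered the co-culture libraries was not examined here. In co-culture replicates 1 and 2, Krt19, Tagln and Hbegf were above all controls and Fabp7 was below them, while replicate 3 lay nearer to the controls. Krt19 (ENSMUSG00000020911), a keratin of simple and ductal epithelium, was at 6.43 ± 0.247 FPKM (SD, n = 3) in the controls and at 26.2, 154.3 and 11.2 in co-culture replicates 1, 2 and 3. Tagln, an actin-binding protein of smooth muscle and myoepithelium, was at 3.63 ± 3.66 (SD, n = 3) in the controls and at 25.0, 239.9 and 1.40 with co-culture. Hbegf, a ligand of the EGF receptor, was at 0.896 ± 0.604 (SD, n = 3) in the controls and at 4.32, 62.5 and 0.639. Fabp7, a fatty acid binding protein of neural progenitors, was at 113.7, 251.2 and 158.2 in the controls and at 35.3, 24.4 and 214.9 with co-culture.

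No co-culture gene passed the test when the 3 libraries of each group were compared without pairing (limma, adjusted p under 0.05, 0 of 425 genes tested, 86 at an unadjusted p under 0.05). With the replicate number as a block, 39 genes passed, of which 38 rose and 1, the predicted gene Gm10273, fell. Without co-culture replicate 3, 330 of 449 genes passed, 284 higher and 46 lower. With both libraries numbered 3 left out, a setting added after seeing the data, 2 of 450 genes passed, and 0 with the block (314 and 340 at an unadjusted p under 0.05).

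The listed genes largely followed a rule on pairs 1 and 2. Of the 546 genes, 390 were at least doubled in co-culture replicate 1 over control 1 and in replicate 2 over control 2, 109 were at least halved in both pairs, and 47 were neither. Changes in pairs 1 and 2 are therefore not independent evidence of direction. The same holds for the calls, standard errors and adjusted p-values of the co-culture fits, with or without the block, which rest in part on these pairs. Pair 3, which such a rule does not use, differed from the other pairs. There, 79.7% of the 390 doubled genes were higher in co-culture, with a median log2 difference of 0.21, and 30.0% were at least doubled. Of the 109 halved genes, 49.5% were lower in pair 3 and 14.7% at least halved. Of the 47 genes that were neither, 59.6% were also higher in pair 3, with a median log2 difference of 0.13. Control 3 lay at -0.25 from the other controls over these 47 genes (median log2). A low control 3 can therefore raise the share of higher genes in pair 3, so the 79.7% does not measure co-culture alone.

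**Figure D1:**
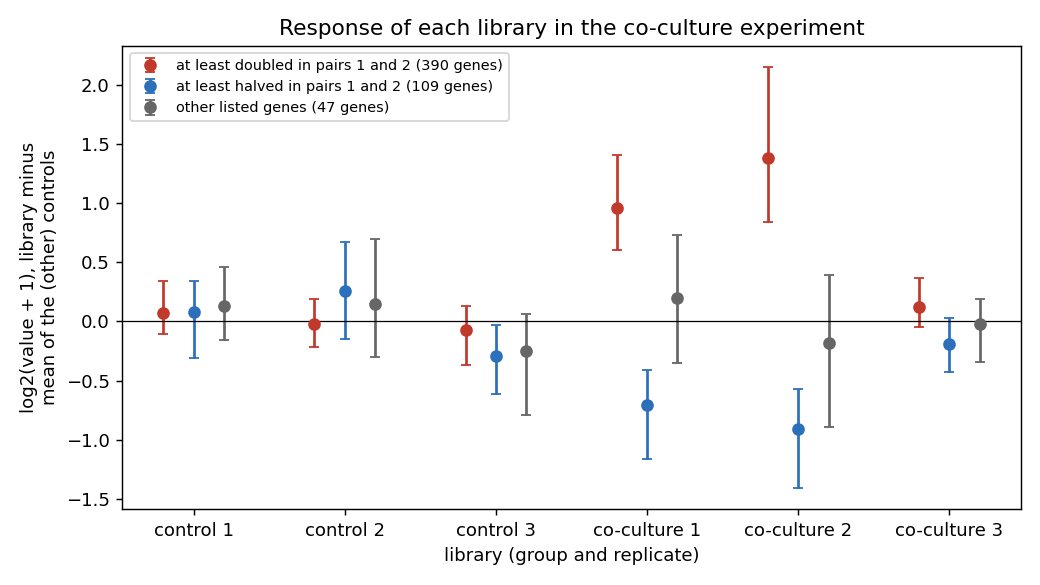
Median log2(value + 1) of each library (horizontal axis: group and replicate) minus the mean of the controls, for control libraries minus the mean of the other controls; bars are quartiles over genes, and colours are genes at least doubled (390), at least halved (109) or neither (47) in pairs 1 and 2. Over the doubled genes, co-culture replicates 1 and 2 lie at 0.96 and 1.38 and replicate 3 at 0.12, with the controls between -0.07 and 0.07.

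In the blocked fit, the 10 largest rises with non-overlapping groups were Fosl2, Slc2a3, Krt19, Perp, Gpc4, Rnf128, Col12a1, Pdgfa, P4ha2 and Arhgap29. The listed genes appear to have been chosen on pairs 1 and 2, so adjusted p-values of this fit can overstate the evidence. Fosl2, a transcription factor of the AP-1 family, rose by 2.59 on the log2 scale (SE 0.59, limma adjusted p = 0.00549). Slc2a3, a glucose transporter, rose from 160.8 ± 86.7 to 861.6 ± 500.4 FPKM (SD, n = 3), with co-culture replicates at 814.8, 1383.7 and 386.3. Krt19 rose by 2.32 (SE 0.61, adjusted p = 0.0115), and Perp, a desmosome-associated protein of stratified epithelia, by 2.19 (SE 0.57, adjusted p = 0.0115). Col12a1, a fibril-associated collagen, and P4ha2, a collagen prolyl hydroxylase, rose by 2.06 and 1.90. These sizes rested in part on co-culture replicate 2. In the fit without it and without the block, Fosl2 was at 1.57, Krt19 at 1.29, Perp at 1.33, Pdgfa at 1.03, Hbegf at 0.69, Tagln at 1.05 and Krt20 at 0.48. Without co-culture replicate 3, Krt19 was at 3.13 and Tagln at 4.37. Krt19 lies on chromosome 11 at 100140810 to 100148665, on the minus strand (GRCm38, GENCODE M21), Fosl2 on chromosome 5 at 32135801 to 32157842, and Slc2a3 on chromosome 6 at 122727809 to 122801640.

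Of the genes in the fixed lists, 44 were tested in co-culture. Over all genes, none passed without the block, and 11 passed with it. In the blocked limma fit, 179 of all 425 tested genes had an unadjusted p under 0.05. Passes adjusted over a short list alone therefore say little about that list. Adjusted over the list alone, without the block, 1 tested gene each passed in the salivary bud, ductal, oral surface ectoderm, neural crest and p53 response lists, and 2 passed in the stratified epithelium list, all higher. The ductal gene is Krt19, which also stands for the salivary bud list. In the same way, 1 gene each was lower in the lists of FGF ligands and receptors (Fgf15) and of retinoic acid response (Crabp2). The ductal list and these last lists had 1 tested gene each, so no adjustment applied. Set against the other tested genes, the fitted directions of none of the 6 lists with at least 3 tested members passed Fisher's exact test (two-sided, adjusted p from 0.858 to 1). The branching morphogenesis list had 5 tested members, of which Hbegf, Pdgfa and Nrg1 rose in the blocked fit (3 also when adjusted over the list alone) and Bmp7 and Eda did not pass. Hbegf rose by 2.16 (SE 0.58), Pdgfa by 1.92 (SE 0.60) and Nrg1 by 1.73 (SE 0.58), each with 3 libraries per group. Of 2 tested myoepithelial genes, Tagln and Acta2 (smooth muscle actin) both rose in the blocked fit, by 2.69 and 1.58, but neither was above its control in pair 3: Tagln was at 1.40 against 1.47, and Acta2 was listed at 0 in both libraries. Of 3 endothelial genes, the VEGF receptor Flt1 rose by 1.43 in the blocked fit, and Kdr and Tek did not pass over all genes. All 3 passed in the blocked fit when adjusted over the list alone. Of 3 p53 response genes, Trp53inp1 rose in the blocked fit, and all 3 passed there when adjusted over the list alone. Krt19 was the 1 of 3 tested salivary bud progenitor genes that passed with the block, and Perp the 1 of 2 oral surface ectoderm genes. None of the 5 tested FGF response genes (Phlda1, Spry1, Egr1, Spry2 and Etv5) passed with the block. Their fitted log2 changes had a median of 1.22, against 0.83 over all tested genes. With quantile normalization these medians were 0.35 and 0.22. Under quantile normalization Spry2 and Etv5 turned, to -0.21 and -0.27. Neither neuroectoderm gene passed with the block over all genes: Fabp7 fitted at -1.51 and Hes5 at -1.17, and 1 of them passed when adjusted over the list alone.

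The authors' deposited table of pathways in genes higher with co-culture holds the MAPK signaling pathway with 11 of 64 annotated genes, an enrichment factor of 5.45 with a q-value of 0.000103. The set was chosen by the authors on these libraries and is not independent evidence of direction. The genes are Pdgfb, Tek, Epha2, Csf1, Egfr, Nr4a1, Fas, Pdgfa, Flt1, Tgfa and Kdr. All 11 were at least doubled in pairs 1 and 2, and 9 were higher in pair 3. In the fit here 0 of the 11 passed without the block, 5 rose with the block (Pdgfb, Epha2, Fas, Pdgfa and Flt1), and 11 passed without co-culture replicate 3. The same deposited table gives 2 genes for TGF-beta signaling (Fst and Thbs1), with an enrichment factor of 3.2 and a q-value of 0.29. For Wnt signaling it gives 2 genes (Nfatc2 and Gpc4), a factor of 1.61 and a q-value of 0.436. For mTOR signaling it gives 1 gene (Lpin1), a factor of 0.86 and a q-value of 0.591. Unlike that of MAPK signaling, these q-values give no evidence of enrichment.

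The authors' panel of 12 genes holds epithelial, secretory and signalling genes. Krt19, the intermediate filament gene Krt20 and Acta2 rose in the blocked fit. The other genes with a test (Chrm3, a muscarinic receptor of the secretory response, Rdh10, Lama5, Spry2, Etv5, Twsg1 and Bmp7) passed neither without nor with the block. Spry2, an inhibitor of FGF signalling, was at 18.9, 19.1 and 13.5 FPKM with co-culture and at 10.7, 12 and 10.4 in the controls. Rdh10, an enzyme of retinoic acid synthesis, was at 4.05, 5.61 and 2.35 against 2.20, 2.02 and 1.27. Fgf10, the ligand that drives salivary branching, stayed below 1 FPKM in every library (0.532, 0.453 and 0.229 against 0.228, 0.151 and 0.186) and was not tested, like the water channel Aqp3. Sox10, a regulator of salivary progenitors and neural crest, was at 2.59 ± 2.09 in the controls and 1.80 ± 1.35 with co-culture (SD, n = 3) and did not pass (limma adjusted p = 0.585, 0.535 with the block).

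**Figure D2:**
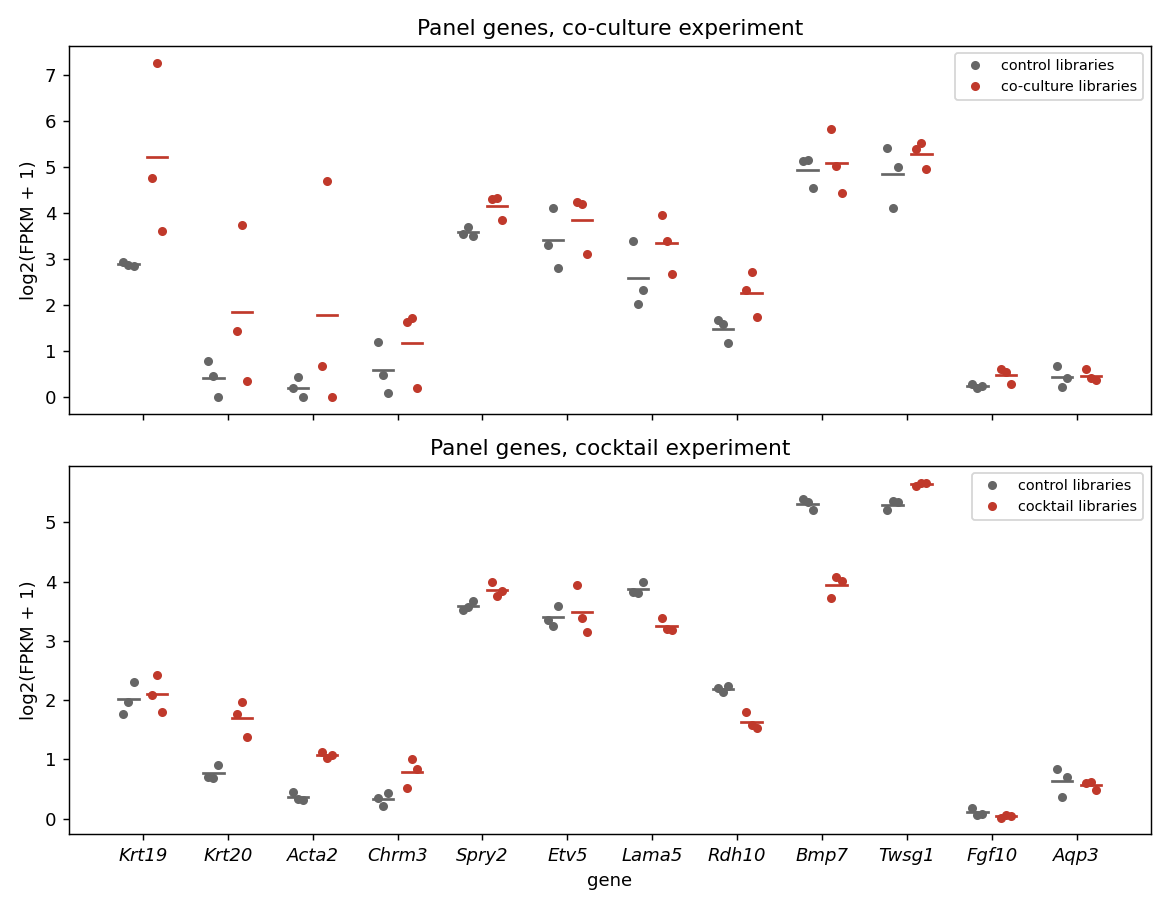
log2(FPKM + 1) of the 12 panel genes in each library (points; lines are means of 3 libraries), with the co-culture experiment above and the cocktail experiment below, controls in grey and treated libraries in red. Krt19 reaches 154.3 FPKM in 1 co-culture library, while its cocktail libraries (3.37 ± 0.954 FPKM) overlap their controls (3.08 ± 0.787).

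The second comparison asked what the cocktail changed. Igtp (ENSMUSG00000078853), an interferon-inducible GTPase, rose from 0.571 ± 0.154 to 366.3 ± 2.25 FPKM, the guanylate-binding protein gene Gbp2 from 0.179 ± 0.0989 to 209.6 ± 3.67, and Psmb8, a subunit of the immunoproteasome, from 0.0868 ± 0.0752 to 134.2 ± 6.11 (SD, n = 3 each). The largest falls included Iapp, Lypd1, Dact2, Car4, Wnt1, Tfap2c, Colec12 and Emp1. Wnt1, a ligand of the dorsal midline of the neural tube, fell from 96.2 ± 3.28 to 26.3 ± 2.54, and Colec12, a collectin receptor, from 33.8 ± 3.21 to 9.05 ± 2.14 (SD, n = 3 each).

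Of 536 genes tested, 534 passed (limma, adjusted p under 0.05), 316 higher and 218 lower, in a table that the authors had already limited to changed genes. Under quantile normalization of these selected genes, 240 were higher and 231 lower. The 2 that did not pass, Krt19 and Etv5, belong to the panel and are outside the list of changed genes. The cocktail list of the authors' deposited table counts 363 genes up and 270 down. With an absolute log2 fold change of at least 1 also required, 319 genes passed, and with a filter at a mean of 5, 255 of 256 did.

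The other rises among the 10 largest were Tgtp1, Tgtp2, Iigp1, Irgm1, Gbp2b, Gbp7 and Gbp6. Tgtp1, Tgtp2 and Iigp1 were listed at 0 in all controls and reached 217.4 ± 16.5, 193.9 ± 13.5 and 153.3 ± 4.98 FPKM (SD, n = 3). Igtp rose by 7.87 on the log2 scale (SE 0.09, limma adjusted p = 8.71e-12) and Psmb8 by 6.96 (SE 0.09, adjusted p = 1.50e-11). Tgtp1 and Tgtp2 are near-identical copies on chromosome 11 (48985327 to 48994172 and 49057194 to 49064206, GRCm38), and the Gbp genes form a family, so the split of reads between such genes is uncertain. Igtp lies on chromosome 11 at 58199556 to 58207591, and Psmb8 on chromosome 17 at 34197721 to 34201454. Among the falls, Iapp fell by 2.90 (SE 0.17, adjusted p = 4.88e-07), Lypd1 by 2.08 (SE 0.13), Car4, a carbonic anhydrase, by 1.90 (SE 0.27) and Tfap2c, a transcription factor of surface ectoderm, by 1.82 (SE 0.09). Iapp lies on chromosome 6 at 142298423 to 142303961 and Wnt1 on chromosome 15 at 98789857 to 98793837.

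**Figure D3:**
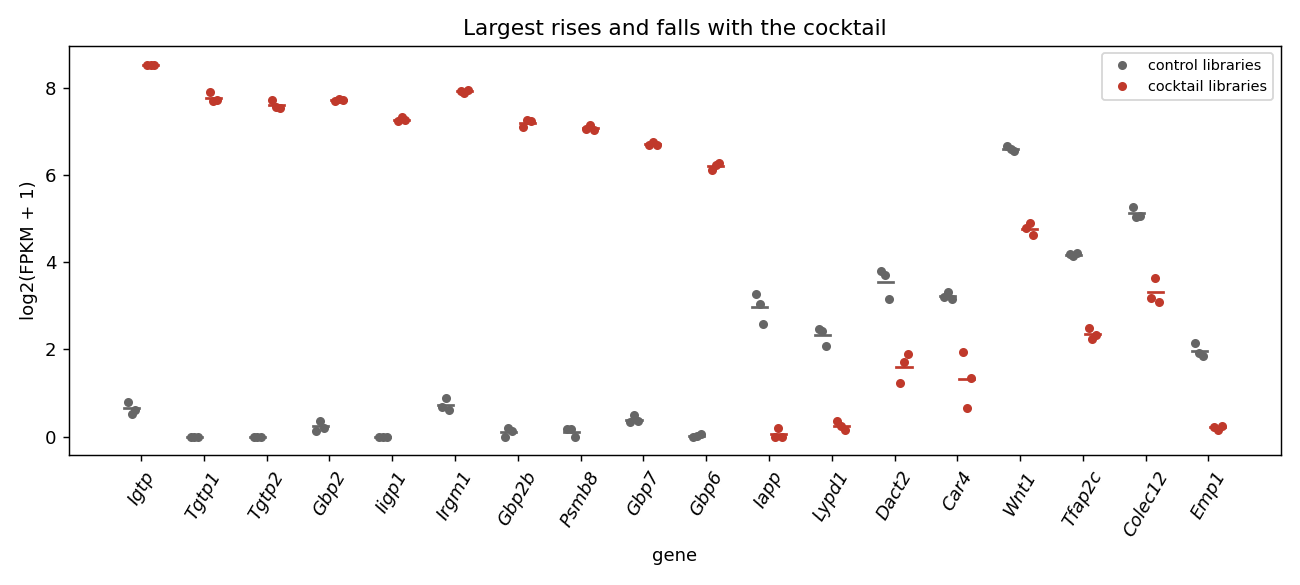
log2(FPKM + 1) of the 10 largest rises (left) and 8 of the 10 largest falls (right) with the cocktail, per library (points; lines are means of 3 libraries), controls in grey and cocktail libraries in red. Igtp stands at 366.3 FPKM in the cocktail group against 0.571 in the controls, and Wnt1 at 26.3 against 96.2.

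Pathway terms from the deposited annotation were unevenly split between higher and lower genes (Fisher's exact test within 327 annotated listed genes, 195 higher and 132 lower). Of 110 terms, 13 leaned to the higher and 5 to the lower genes at an adjusted p under 0.05. Antigen processing and presentation had 22 higher genes and 1 lower (adjusted p = 0.0021), with B2m, the light chain of class I molecules, rising from 31.9 ± 0.871 to 681.0 ± 42.2 FPKM and H2-K1 from 56.6 ± 4.10 to 1358.8 ± 57.3 (SD, n = 3). Influenza A had 20 higher and 0 lower (adjusted p = 0.000897), among them Stat2, Irf9 and Mx2. TNF signaling had 24 higher and 2 lower (adjusted p = 0.00382). Its higher genes include the interferon-inducible GTPases Iigp1, Tgtp1, Tgtp2 and Ifi47 and several predicted or new genes, so the count does not stand for TNF signaling alone. Many of the 13 higher terms, such as antigen processing and presentation and several virus infections, share the same class I genes and are not separate results. Fisher's exact test also counts each gene as independent. Many of these class I genes are related H2 genes that rose together, so the adjusted p-values of such terms can overstate the evidence. Phospholipase D signaling had 0 higher and 8 lower (adjusted p = 0.00851), focal adhesion 3 and 12 (adjusted p = 0.0242), Rap1 signaling 2 and 11 (adjusted p = 0.0242), mTOR signaling 1 and 8 (adjusted p = 0.0287) and PI3K-Akt signaling 8 and 17 (adjusted p = 0.037). The lower genes shared by several of these terms include the receptors Egfr, Kdr and Pdgfra. TGF-beta signaling, with 2 higher and 9 lower genes, missed the threshold (adjusted p = 0.0501), as did MAPK signaling with 6 and 9 (adjusted p = 0.298).

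Of the genes in the fixed lists, 30 were tested with the cocktail and 28 passed. All 4 tested Hox genes rose, the same number as adjusted over the list alone: Hoxc5 from 14.7 ± 3.31 to 45.1 ± 13.5 FPKM, Hoxb6 from 2.03 ± 0.452 to 11.2 ± 5.33, Hoxb8 from 4.25 ± 1.63 to 15.2 ± 7.37 and Hoxb5 from 14.3 ± 4.14 to 36.3 ± 14.8 (SD, n = 3). Under quantile normalization of the selected genes, which moved the median log2 change by -0.58, 1 of the 4 (Hoxb6) passed, and Hoxc5, Hoxb8 and Hoxb5 fitted at 0.25, 0.81 and 0.00. All 3 tested basement membrane genes fell, also adjusted over the list alone: the collagen IV chains Col4a1 by 1.36 (SE 0.07) and Col4a2 by 1.14 (SE 0.07), and the laminin chain Lama5 by 0.62 (SE 0.09). All 3 tested mesenchyme genes fell, also adjusted over the list alone: Twist1 by 1.65 (SE 0.10), Col6a2 by 0.71 (SE 0.13) and Pdgfra by 0.53 (SE 0.09). Of the list's 2 genes below the filter, the authors' deposited table gives Col3a1 a log2 fold change of -1.31 and Col6a3 one of 2.95. Set against the other tested genes, which nearly all passed, the direction of neither list nor that of the Hox list passed Fisher's exact test (two-sided, adjusted p = 0.137 for basement membrane and for mesenchyme and 0.197 for Hox). Both tested oral surface ectoderm genes, Dlx3 and Tfap2c, fell, as did both endothelial genes, Kdr and Cldn5. Of 3 tested FGF response genes, Egr1 and Spry2 rose and Etv5 did not pass, but under quantile normalization none was higher: Egr1 did not pass (0.24), and Spry2 and Etv5 fell. Among lists with fewer tested members, the Wnt response genes Tcf7 and Sp8 and the ductal gene Gstt1 rose, though under quantile normalization Tcf7 turned to -0.79 and Sp8 did not pass (0.20). The neuroectoderm gene Lhx2 and the retinoic acid response gene Stra6 fell. The leukocyte list had 1 tested gene, Cd74, which rose by 1.12 (SE 0.15) to 2.18 ± 0.645 FPKM (SD, n = 3).

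The authors' panel for the cocktail holds 15 genes. Krt20 rose from 0.703 ± 0.153 to 2.31 ± 0.667 FPKM, the transglutaminase gene Tgm2 from 0.654 ± 0.146 to 2.16 ± 0.508 and Acta2 from 0.291 ± 0.0700 to 1.11 ± 0.0690 (SD, n = 3). Tgfb1 and Chrm3 were below the filter of 1 FPKM, and the authors' deposited table gives them log2 fold changes of 1.49 and 1.98. Twsg1, a BMP-binding protein, rose by 0.35 (SE 0.07) and Spry2 by 0.28 (SE 0.09). Both directions turned under quantile normalization of the selected genes, to -1.34 and -0.70. Krt19 (0.09, SE 0.19, limma adjusted p = 0.645) and Etv5 (0.09, SE 0.19, adjusted p = 0.652) did not pass. Bmp7 fell by 1.38 (SE 0.11), Sema3c, a guidance factor, by 0.91 (SE 0.10), Lama5 by 0.62 and Rdh10 by 0.56 (SE 0.11). Fgf10 was at 0.0754 ± 0.0453 in the controls and 0.0293 ± 0.0140 with the cocktail (SD, n = 3), and Aqp3 at 0.565 ± 0.253 and 0.486 ± 0.0757. Neither reached the filter.

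The third comparison set the cocktail against co-culture, which it was meant to replace. Across 48 genes, Spearman's rho of the log2 fold changes was 0.22 and Pearson's r was 0.25, and 30 genes (62.5%) had the same sign. Genes are not independent replicates, and the tables were normalized separately. Socs1, Stat3 and Csf1 were at least doubled in co-culture pairs 1 and 2 and rose with the cocktail. Kdr and Egfr were at least doubled in those pairs and fell with the cocktail. Gsx2 and Prdm13, transcription factors of dorsal neural progenitors, were at least halved in them and rose with the cocktail. Of the co-culture genes in the authors' deposited list for the cocktail, 66 in all, those doubled in pairs 1 and 2 were listed as up in 29 cases and down in 15, and those halved as up in 7 and down in 9 (Fisher's exact test, two-sided, odds ratio 2.49, p = 0.145). No difference between the 2 experiments was tested for single genes.

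**Figure D4:**
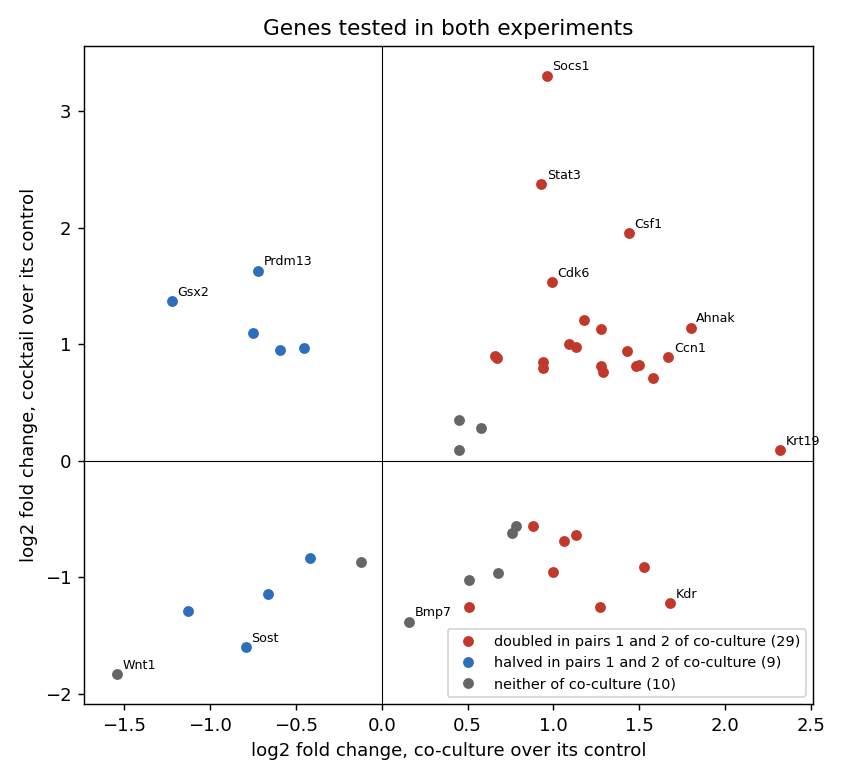
log2 fold change (log2(value + 1) scale) with co-culture (horizontal axis) and with the cocktail (vertical axis) for the 48 genes tested in both experiments, coloured by whether they were doubled, halved or neither in co-culture pairs 1 and 2. The points spread over all 4 quadrants, with Krt19 at 2.32 and 0.09.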

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

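These genes were picked by a rule fixed beforehand: every treated library lay on one side of its controls in the co-culture experiment and on the opposite side in the cocktail experiment. The difference between the experiments was not tested. Values are log2 changes without a filter on low values. Rdh10, an enzyme of retinoic acid synthesis, was at 0.78 with co-culture and -0.56 with the cocktail. Under quantile normalization the former was 0.08 (limma adjusted p = 0.874) and the latter -1.04. Ccno, a cyclin of multiciliated cells, was at 0.59 and -0.72, and Fgf10, below 1 FPKM throughout, at 0.24 and -0.06. Eda, a ligand in ectodermal organ development, was at -0.59 and 0.95, the cytokine Il18 at -0.75 and 1.10, and Wnt8b at -1.0 and 0.40. These are 6 of 74 genes in both tables, and 13 others were fully separated in the same direction in both. Both tables hold genes chosen for change, so no number to be had by chance can be set beside these. No search for single outlying libraries was run by a rule in groups of 3, and co-culture replicate 3 was examined because it lay with the controls.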

How the results depend on the processing

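Chosen after the results were seen were the settings that left out both libraries numbered 3, those that used only genes doubled or halved in pairs 1 and 2 or only the list of changed genes, the authors' fold change for the correlation between experiments, the left-out libraries for all correlations and the pseudocount for those within groups. Leaving out 1 library at a time gave 0 to 330 genes past the threshold (0 to 284 higher, 0 to 46 lower). The 330 came without co-culture replicate 3, and 1 gene, Slc2a3, passed without control replicate 1. The replicate block gave 39 genes (38 higher, 1 lower). Leaving out both libraries numbered 3 gave 2 higher genes (Gm28036 and Gm49450). All other co-culture settings gave 0, as in the main test. List members past the threshold were 0 in the main test, 0 to 34 with 1 library left out (34 without co-culture replicate 3) and 11 with the block. For the cocktail, leaving out 1 library gave 530 to 536 genes (312 to 316 higher, 216 to 221 lower). Requiring an absolute log2 fold change of at least 1 gave 319 (210 higher, 109 lower), and a filter at a mean of 5 gave 255 (170 higher, 85 lower), in both cases by construction. List members were 28, against 17 with the fold requirement and 27 to 28 with 1 library left out. Quantile normalization shifted the median log2 change of the selected genes by -0.58 in the cocktail experiment and by -0.61 in co-culture. It turned 24 called cocktail genes, among those named Twsg1 to -1.34 and Spry2 to -0.70, and Etv5, not called before, to -0.81. It also ended 64 calls, all of higher genes, among them Hoxb5, Hoxb8 and Hoxc5. A method that forces selected genes into one distribution reduces the direction they share. Adjusted over the list alone, further list members passed with the block, among them all 3 tested immediate early genes (Fos, Egr1 and Junb). In that limma fit, 179 of all 425 tested genes had an unadjusted p under 0.05. The correlation between experiments was 0.22, against 0.32 over all shared genes, -0.01 over genes doubled or halved in pairs 1 and 2, and 0.11 to 0.29 with 1 library left out. The cause was not tested. Mean correlation within groups was 0.889 in co-culture (0.862 to 0.929 with 1 library left out) and 0.990 with the cocktail (0.989 to 0.990, and 0.984 at a pseudocount of 0.1). Set tests with camera and fry were not run because the tables are selected, count tools were not run, calls by the authors for co-culture were not used here, and the correlation over genes called in both experiments was not run, since without the block no gene was. With the block, Krt20, Acta2, Fas and Ahnak were higher in both. Depth was not analysed here, and 3 libraries per group limit precision.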

Other observations

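The gene groups and tests below were chosen after the results were seen, except the counts over other splits of all 6 libraries. The groups were written from the listed genes themselves, so their counts describe the tables and are not independent evidence of a direction. With the cocktail, all 17 tested interferon-inducible GTPases rose, as did all 23 genes of the class I antigen pathway and all 18 tested antiviral interferon-response genes. Under quantile normalization 17 GTPases, 22 class I genes and 17 antiviral genes were higher, Psme1 turned to -0.38 and Eif2ak2 did not pass. The transcription factors Irf1 and Irf8 rose from 3.62 ± 0.509 to 145.5 ± 2.81 and from 0.753 ± 0.0257 to 99.4 ± 4.24 FPKM (SD, n = 3). Of the class II pathway, Cd74 reached 2.18 ± 0.645 FPKM and the class II transactivator Ciita, listed at 0 in all controls, 0.273 ± 0.0734. Stat3 and its feedback inhibitor Socs3 rose by 2.37 (SE 0.09) and 1.82 (SE 0.10). The feedback inhibitor Socs1 rose by 3.30 (SE 0.13).

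All 9 tested genes of the neural roof plate, the dorsal midline of the neural tube, fell with the cocktail (median -1.28, and 9 fell under quantile normalization), among them Lmx1a from 28.2 ± 1.67 to 8.50 ± 1.15 FPKM and Gdf7 from 65.8 ± 5.53 to 26.8 ± 4.35 (SD, n = 3). All 8 tested transcription factors of dorsal neural progenitors rose (median 1.21), but under quantile normalization 5 did, Neurog1 turned to -0.62, and 2, among them Onecut3, did not pass. The rises included Prdm13 from 4.01 ± 0.511 to 14.7 ± 3.24 and Ptf1a from 0.0859 ± 0.0269 to 2.12 ± 0.714. In co-culture, 10 tested genes of the AP-1 and Egr families fitted above 0 (median 1.44, 1 past the threshold with the block, 10 without replicate 3), as did 13 targets of YAP and serum response factor (median 1.3, 3 past the threshold with the block). The whole table leaned up (median 0.83), neither direction stood out from it (Fisher's exact test, two-sided, adjusted p = 0.117 each), and under quantile normalization the medians were 0.66 and 0.75. Ccn1 was at 89.5, 97.4 and 14.0 FPKM in co-culture replicates 1, 2 and 3 and at 15.4 ± 4.69 in the controls (SD, n = 3), and Thbs1 at 46.5, 110.3 and 3.46 against 4.28 ± 1.31.

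Co-culture replicate 3 lay with the controls. A swap of labels with control 3 is argued against, since that control, whose values did not enter the choice of the 390 doubled genes, lay at -0.07 from the other controls over them (median log2), against 0.96 and 1.38 in co-culture replicates 1 and 2; a swap with control 1 or 2 stays open, because those are low in these genes by the choice (at most 0.07). Noise of genes near 0 stays open: over the 121 doubled genes with a mean of at least 5, replicate 3 was at 0.18 and replicates 1 and 2 at 1.49 and 2.28, but the choice of these genes raised the latter. A smaller response of that culture and an untreated library labelled as co-culture cannot be told apart: the share of doubled genes higher in replicate 3 was 58.2%, 66.2% and 79.7% against controls 1, 2 and 3 (up to 61.8% between controls), and that of halved genes lower was 64.2%, 78.0% and 49.5% (up to 71.6% between controls). The labels name no difference between replicates, so no biological explanation was tested.

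The interferon-type response to the cocktail may reflect a factor of the cocktail, which stays a hypothesis, since its composition is not given in the sources used here. Reads shared between near-identical gene copies concern, by definition, only genes with such copies. Over 15 genes without them, the authors' deposited log2 fold change had a median of 5.39 and a lowest value of 2.12. All 15 rose under quantile normalization too. They were picked from the changed genes after the results were seen, so their values describe them and are no test of shared reads. For the size of the rise in single interferon-inducible GTPases (median 10.27) shared reads stay open, because a stronger response of these genes would give the same values. All 17 tested GTPases rose, by a median log2 change of 6.18 in the fit here, and 0 fell. Shared reads only pass from 1 copy to another. These values therefore argue against shared reads for the rise of the GTPases as a set. Immune cells in the aggregates stay open, because 1 leukocyte marker of the 14 fixed beforehand (Cd74, at 2.18 FPKM) was in the table, and genes outside a table of selected genes exclude nothing.

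A candidate explanation for the genes in both tables is that the cocktail moved them in the direction of co-culture. The odds ratio was 2.49 (Fisher's exact test, p = 0.145), which does not settle it, and the correlation of the changes was -0.01 among genes doubled or halved in co-culture pairs 1 and 2.

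Other splits of the libraries are too few for a share under 0.05, and the tables hold genes chosen on the real groups, which favours the real split. For co-culture, the real split gave 0 genes, like 8 of the others, and the highest other gave 2, so all 10 splits gave as many, as any split must beside a count of 0. At an unadjusted p under 0.05 the real split gave 86 genes, and the split that exchanges co-culture replicate 3 with control 1 gave 114. With the pairs kept, 4 splits part all pairs: the real one gave 39 genes, 1 split in all with as many, and the highest other, with the libraries of pair 3 exchanged, gave 2. For the cocktail, the real split gave 534 genes, 1 of 10 splits with as many, and the highest other gave 0.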
